A study of Mus musculus with 5 samples.

How the data were processed

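The material was RNA from mouse peritoneal macrophages on 5 Affymetrix MG-U74Av2 arrays, 1 array per sample. Per the labels, the samples were an untreated control, 2 pools of mice given poly IC and 2 pools of mice given poly IC plus ethanol, and samples were placed in groups by their titles. Per the labels' descriptions, the treated mice were females of a C57Bl/6 by C3H F1 cross, aged 12 weeks, and doses were 0.1 mg poly IC per mouse and 6 g ethanol per kg. The label of the naive control gives no sex or age. The poly IC dose is not stated for the first poly IC pool, and the time between treatment and cell harvest, the route of poly IC and the number of mice per pool are not given in the sources used here. Per the labels, labelled cRNA was hybridised, scanned and summarised with Affymetrix Microarray Suite 5.0, and Data Mining Tool 3.0 was used by the submitters. The deposited values are intensities: 1 signal per probe set and array, on a linear scale, which per the labels had been scaled globally to a target of 2500. The trimmed mean of each array lay between 2501.5 and 2502, as that scaling gives. Global scaling fixes the mean of each array, so a broad change in RNA content cannot be seen in these values, and the offset added before the logarithm compresses the folds of dim genes. Detection calls were not used here.

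Probe sets were named through the platform annotation. Of 12488 probe sets, 66 were controls. Of the other 12422, 10833 had 1 gene symbol, 396 had several and 1193 had none listed, and only those with 1 symbol were used. Symbols were updated by Entrez ID through a RefSeq gene table of assembly GRCm38.p6, used only for names, in which 10817 were found. Probe sets with a mean signal over the 5 arrays under the 40th percentile (513) were left out, which kept 6675. For each gene the probe set with the highest mean signal was used, which gave 5581 genes. For 921 genes more than 1 probe set passed the filter, and among called genes the other probe sets had the same sign in 93.9% of 131 cases for ethanol against poly IC, 88.1% of 403 for poly IC against naive and 85.8% of 226 for ethanol against naive. Where another probe set of a printed gene did not pass, its value is printed.

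Signals were analysed as log2(signal + 250) without further normalization. A linear model with a mean for each of the 3 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p-values were two-sided and adjusted by Benjamini-Hochberg over all genes. The model left 2 residual degrees of freedom, to which the prior added 7.63. The single naive array added none and was assumed to vary like the others. A gene was called at adjusted p under 0.05. For a gene whose mean in the lower group lay below the brightest of 19 unspiked control probe sets on the arrays of that group (299.6 to 443.8 by array), the fold was given as a lower bound, the mean of the higher group over the signal of that control. List medians were repeated with such genes at their bounds, which shifted them by at most 0.291 log2 units. Gene lists were compared with all other tested genes by camera with a preset correlation of 0.01, in 23 of 25 lists with at least 4 tested genes. The calls were repeated with an estimated correlation and with fry. With an estimated correlation camera uses only the 2 residual degrees of freedom, so hardly any list can pass in that setting. For ethanol against poly IC, the MHC class II list had an estimated correlation of 0.00927, below the preset 0.01. Its unadjusted camera p still went from 0.00279 to 0.0952. A call lost in that setting therefore does not tell whether correlation between genes produced it. Adjusted p-values over the members of a list alone were computed as well.

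The ethanol effect on poly IC-induced genes was a cross-fitted median, in which genes were chosen on one poly IC array and measured against the other. It was set beside 10000 random lists matched on signal. Overlaps and correlations between comparisons that share arrays were set beside simulations without effects and beside the overlap of independent lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

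The groups, the comparisons and their tests, the lists, the naming rule and the alternatives were fixed before the data were examined. List tests for poly IC plus ethanol against naive, the mirror measure on lowered genes, and the overlaps and correlations between comparisons were not among the tests fixed then. Named genes were the 10 with the largest rise and the 10 with the largest fall among called genes in each comparison, the 3 members of each list with the largest absolute moderated statistic, and a fixed set of genes of interferon and cytokine biology named in every comparison. Only a part of the genes this rule selects is printed, and that part was picked after the values were seen. Genes named outside it are said to have been named or chosen after their values were seen. Of the fixed set, 1 item is not reported here, Tlr3 had no probe set with that symbol alone, and Ifnb1 and Tsc22d3 fell below the filter, Tsc22d3 with signals of 106 on the naive array, 158 and 727 on the poly IC arrays and 386 and 434 on the ethanol arrays. Alternatives were an offset of 16 or 1000, no filter or one at the 60th percentile, quantile normalization, median-centred arrays, eBayes without the trend, the mean over the probe sets of a gene, a threshold of 0.10, each array left out in turn, the replicate number as a block and the 4 treated arrays alone.

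The procedures were tested on simulated data for 5581 genes in 20 simulations with the real group sizes. For ethanol against poly IC, of 100 genes moved by 1 log2 unit 77.8 were called on average, and of 100 moved by 2 log2 units 97.4. On average 12.8 unchanged genes were called, a false share of 6.76%, above the nominal level. For poly IC against naive, 94.1% of 1160 genes at least 1 log2 unit apart were called. For ethanol against poly IC, the cross-fitted median with no effect was -0.0029, against -0.0336 without cross-fitting. In 1 further simulated data set, a list of 30 genes moved by 0.5 gave a camera p of 1.99e-31, and an unmoved list of 30 gave 0.889. Noise was independent between genes there, whereas the real interferon-stimulated and neutrophil lists had estimated correlations of 0.245 and 0.349. The check therefore does not show how often camera calls an unmoved list of correlated genes.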

Results

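RNA from mouse peritoneal macrophages was hybridised to 5 Affymetrix MG-U74Av2 arrays, which carry short oligonucleotide probe sets for mouse transcripts. The series asks how acute oral ethanol alters gene induction by poly IC (polyinosinic polycytidylic acid), a synthetic double-stranded RNA that cells sense as if it were viral. The arrays fell into 3 groups: 1 array from untreated (naive) animals, 2 arrays from mice given poly IC and 2 arrays from mice given poly IC plus ethanol. Each of the 4 treated samples was a pool of mice, so p-values of single genes measured the spread between pools and not between animals. Camera p-values of lists with the preset correlation measured the spread between genes. Small list p-values are therefore not evidence of replication across pools. The labels did not state a pool, sex or age for the naive sample, and its variance was assumed to equal that of the treated groups. A difference in sex or age between naive and treated mice cannot be told apart from the effect of poly IC. The number of arrays limited the precision of every comparison.

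Each array carried 12488 probe sets, scaled by the submitters to a common target. The median signal was 836 on the naive array, 785 and 769 on the poly IC arrays, and 798 and 902 on the ethanol arrays. Across 5581 tested genes, which are not independent replicates, the log2 signals of the poly IC pair correlated at r = 0.975 and those of the ethanol pair at r = 0.965. The naive array correlated at 0.793 and 0.783 with the poly IC arrays and at 0.861 and 0.843 with the ethanol arrays. Ratios of 3' to 5' probe sets for actin lay between 1.04 and 1.15. Signal from the 3' probe set for 18S ribosomal RNA differed between pools of one group. It was 7277 in the naive sample, 5113 and 66548 in poly IC replicates 1 and 2, and 8225 and 19415 in ethanol replicates 1 and 2. Means are given as signals ± SD with n = 2 for either treated group, and naive signals have n = 1. Log2 differences are on the log2(signal + 250) scale, which understates the change of dim genes.

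Poly IC against naive gave the induction on which ethanol was then tested. Interferon-stimulated genes were among those that rose most. Ifit1, which binds viral RNA lacking a self cap, had a signal of 31 on the naive array, below the brightest unspiked control probe set. After poly IC it was 70276 ± 5260 (n = 2), at least 233-fold higher (adjusted p = 1.08e-09). Rsad2, which encodes the antiviral enzyme viperin, went from 279 to 62041 ± 3444, at least 206-fold. Ifit2 and Ifit3 also started below that control and rose at least 114-fold and at least 186-fold, and Cmpk2 rose by 6.23 log2 units. Isg15, a ubiquitin-like modifier, rose from 1140 to 78202 ± 16196 (log2 difference 5.80, SE 0.18), and Irf7, a transcription factor that amplifies interferon production, rose by 3.57 (SE 0.24). Of 42 tested members of the interferon-stimulated list, 36 rose and 1 fell over all genes tested, and also 36 and 1 when adjusted over the list alone. Their median was 2.45 (camera adjusted p = 2.93e-33, and adjusted p = 0.273 with an estimated correlation). The member that fell was Ifi30, a lysosomal thiol reductase (-1.19, SE 0.20), named after its value was seen. All 9 tested interferon-gamma-inducible GTPases, which act on vacuoles of intracellular pathogens, rose, also when adjusted over the list alone. Their median was 3.30 (camera adjusted p = 1.09e-13, and adjusted p = 0.273 with an estimated correlation). Among them were Iigp1 (1114 to 59382 ± 12240), Ifi47 (3544 to 47073 ± 1428) and Irgm2 (3959 to 41344 ± 2676). Signals of Ifnb1, the interferon-beta gene, were below the filter, at 133 on the naive array, 97 and 787 on the poly IC arrays, and 700 and 471 on the ethanol arrays.

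Inflammatory cytokine and chemokine genes rose in the same comparison. Il1rn, the secreted antagonist of interleukin-1, rose from 469 to 78870 ± 4983 (n = 2, log2 difference 6.78, SE 0.16, adjusted p = 2.11e-09). Acod1, which makes itaconate, rose from 230 to 82944 ± 8530, at least 275-fold. Il1a and Il1b rose by 5.51 (SE 0.16) and 5.37 (SE 0.25) log2 units and Tnf by 3.21 (SE 0.21). From naive signals below the brightest unspiked control, Il6 rose at least 55.4-fold, Il10 at least 6.76-fold and Il12b at least 5.27-fold. Nos2, the inducible nitric oxide synthase, also started below it and rose at least 4.76-fold (adjusted p = 0.00455). The Nos2 call was lost without poly IC replicate 2 (adjusted p = 0.0596), the highest p of its alternatives, which went down to 6.56e-05. In the list of inflammatory cytokines and NF-kB targets, 39 of 44 members rose and 1 fell, and 40 and 1 when adjusted over the list alone. Their median was 2.32 (camera adjusted p = 1.52e-32, and adjusted p = 0.273 with an estimated correlation). Neutrophil markers rose in the same comparison (median 1.79, camera adjusted p = 4.19e-08, and 0.316 with an estimated correlation). The gene that fell was Ltb, lymphotoxin beta, which is also on the dendritic cell list (-2.32, SE 0.18). Of 19 chemokines, 14 rose, and 15 rose when adjusted over the list alone. Their median was 2.36 (camera adjusted p = 4.86e-14, and adjusted p = 0.273 with an estimated correlation). Ccl4 (at least 213-fold), Ccl7 (at least 210-fold) and Cxcl10 (at least 165-fold) started below the brightest unspiked control. Ccl5 and Ccl2 rose from 2515 to 77193 ± 10026 and from 2556 to 58536 ± 4617.

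Antigen presentation lists moved in opposite directions with poly IC. For MHC class I, 7 of 14 genes rose, and 8 when adjusted over the list alone. Their median was 0.40 (camera adjusted p = 0.000267, and adjusted p = 0.316 with an estimated correlation). The peptide transporter Tap1 rose by 2.03 (SE 0.15) and the immunoproteasome subunit Psmb10 by 1.25 (SE 0.15). For MHC class II, 10 of 14 genes fell, also when adjusted over the list alone. Their median was -0.66 (camera adjusted p = 0.00244, and adjusted p = 0.31 with an estimated correlation). H2-Ob (-1.86, SE 0.20), H2-DMb2 (-1.38, SE 0.16) and H2-DMa (-1.23, SE 0.14) were among the falls. All 3 of these are also expressed by B cells, whose markers fell in the same comparison (12 of 16, median -1.17).

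Signalling, stress and receptor genes also changed with poly IC. Of 28 Toll-like receptor signalling components, 9 rose and 3 fell, and 9 and 4 when adjusted over the list alone. Their median was 0.32 (camera adjusted p = 0.00742, and adjusted p = 0.476 with an estimated correlation). Cd14, a co-receptor for lipopolysaccharide, and the kinase gene Ikbke rose by 1.53 (SE 0.11) and 2.41 (SE 0.17). The genes that fell, named after their values were seen, were the p38 kinase Mapk14 (-2.06, SE 0.19), Fos (-1.09, SE 0.16) and Irak1 (-0.64, SE 0.21). Of 25 heat shock and endoplasmic reticulum stress genes, 9 rose and 2 fell, the same counts as when adjusted over the list alone. Their median was 0.42 (camera adjusted p = 0.000291, and adjusted p = 0.31 with an estimated correlation). Hspa1b rose by 1.69 (SE 0.19), the chaperone Hspa5 by 0.87 (SE 0.13) and the stress factor Atf3 by 2.20 (SE 0.15). Dnajb1 (-0.95, SE 0.24) and Herpud1 (-0.75, SE 0.25) fell and were named after their values were seen. Of 23 complement and phagocytic receptors, 8 rose and 2 fell, the same counts as when adjusted over the list alone. Their median was 0.20 (camera adjusted p = 0.00244, and adjusted p = 0.522 with an estimated correlation and 0.0739 with fry). Fcgr1 (3.06, SE 0.21), Clec4e (3.01, SE 0.19) and the C5a receptor C5ar1 (2.15, SE 0.16) rose, beside 11 of 16 neutrophil markers (median 1.79). The falls, named after their values were seen, were C3ar1 (-0.89, SE 0.20) and Mertk (-0.80, SE 0.24). Metallothioneins Mt1 and Mt2, which bind zinc and copper, rose by 3.75 (SE 0.13) and 6.03 (SE 0.11). The glucocorticoid-responsive list that holds them missed the threshold (camera adjusted p = 0.0757), with 10 of 29 genes up and 7 down, also when adjusted over the list alone. It passed upward with fry (adjusted p = 0.0261) and with poly IC replicate 1, ethanol replicate 1 or ethanol replicate 2 left out. Its adjusted p ranged from 0.0261 to 0.476 over its alternatives. Smaller falls were lost when 1 array was left out. Without poly IC replicate 1 the log2 differences of Irak1, Dnajb1, Herpud1 and C3ar1 were -0.80, -0.78, -0.71 and -0.72, none of them called. Without poly IC replicate 2 those of Irak1, Herpud1 and Mertk were -0.48, -0.79 and -0.65, also not called. Irak1, Herpud1 and Mertk also lost their calls with median-centred arrays, quantile normalization or no filter, and Irak1 and Herpud1 with eBayes without the trend.

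Markers of other cell types moved with poly IC as well. Of 16 neutrophil markers, 11 rose and 1 fell, and 13 and 1 when adjusted over the list alone. Their median was 1.79 (camera adjusted p = 4.19e-08, and adjusted p = 0.316 with an estimated correlation). The calprotectin subunit S100a8 rose from 564 to 48580 ± 11651 (n = 2, log2 difference 5.89, SE 0.21) and S100a9 from 295 to 25908 ± 7636, at least 85.8-fold. Lcn2, which activated macrophages can also make, rose at least 38.1-fold, but its other probe set did not pass (log2 difference 0.37, adjusted p = 0.416). With 7 members that were below the brightest unspiked control set at their bounds, the neutrophil median was 1.94. Prtn3, named after its value was seen, fell (-1.55, SE 0.22). Of 16 B cell markers, 12 fell and 1 rose, and 13 and 1 when adjusted over the list alone. Their median was -1.17 (camera adjusted p = 3.06e-05, and adjusted p = 0.316 with an estimated correlation). The B cell receptor component Cd79b fell from 62100 to 4436 ± 888 (-3.75, SE 0.20, adjusted p = 5.14e-07) and Spib from 12717 to 1505 ± 385 (-2.90, SE 0.24). Cd83, which activated myeloid cells also carry, rose by 1.77 (SE 0.16). Haemoglobin transcripts were chosen after their values were seen and were too few for a list test. Hba-a1 was 668 on the naive array and 14514 and 26049 on the poly IC arrays (4.42, SE 0.39, adjusted p = 2.15e-05), and Hbb-b2 rose by 3.10 (SE 0.44). The list of resident peritoneal macrophage markers missed the threshold (camera adjusted p = 0.235), with 6 of 23 members up and 4 down, also when adjusted over the list alone. Its falls, named after their values were seen, were Tgfb2 (-2.10, SE 0.23), Mertk, Lgals3 (-0.61, SE 0.17) and Gata6, the transcription factor that defines these cells (7218 to 1169 and 1531, -2.23, SE 0.24). Another probe set for Gata6 did not pass (-0.54, adjusted p = 0.352). The Lgals3 call was lost without poly IC replicate 1 (-0.68) and without replicate 2 (-0.54), and that of Mertk without replicate 2 (-0.65). Both were also lost with median-centred arrays, Lgals3 with eBayes without the trend, and Mertk with quantile normalization or no filter. Outside the lists, genes that fell far were the p53 target Sesn1 (13403 to 960 ± 52, -3.50, SE 0.21) and the transcriptional regulator Lyl1 (-3.49, SE 0.19). The linker histone H1f2 and the regulator Cbfa2t3 fell to means below the brightest unspiked control, at least 14.1-fold and at least 15-fold. Ccr2, the chemokine receptor of inflammatory monocytes, fell by 3.37 (SE 0.37).

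In total, limma called 1775 of 5581 genes between poly IC and naive at adjusted p under 0.05, 654 higher and 1121 lower. Of these, 1058 differed at least 2-fold, and 2358 genes had an unadjusted p under 0.05. The median difference of all genes was -0.156 log2 units. After centring each array on its median the split was 843 higher and 721 lower of 1564. With quantile normalization it was 729 higher and 974 lower, so falls outnumbered rises with that scaling but not with centring. The count was lower when either poly IC array was left out, not only without replicate 2, the pool with the high 18S signal. Of 23 lists tested with camera, 11 passed, 9 up and 2 down. With an estimated correlation, which leaves 2 degrees of freedom for the test, none of them passed, and 4 had an unadjusted p under 0.05. fry, which asks whether the genes of a list move one way without comparing them with other genes, called 14.

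**Figure D1:**
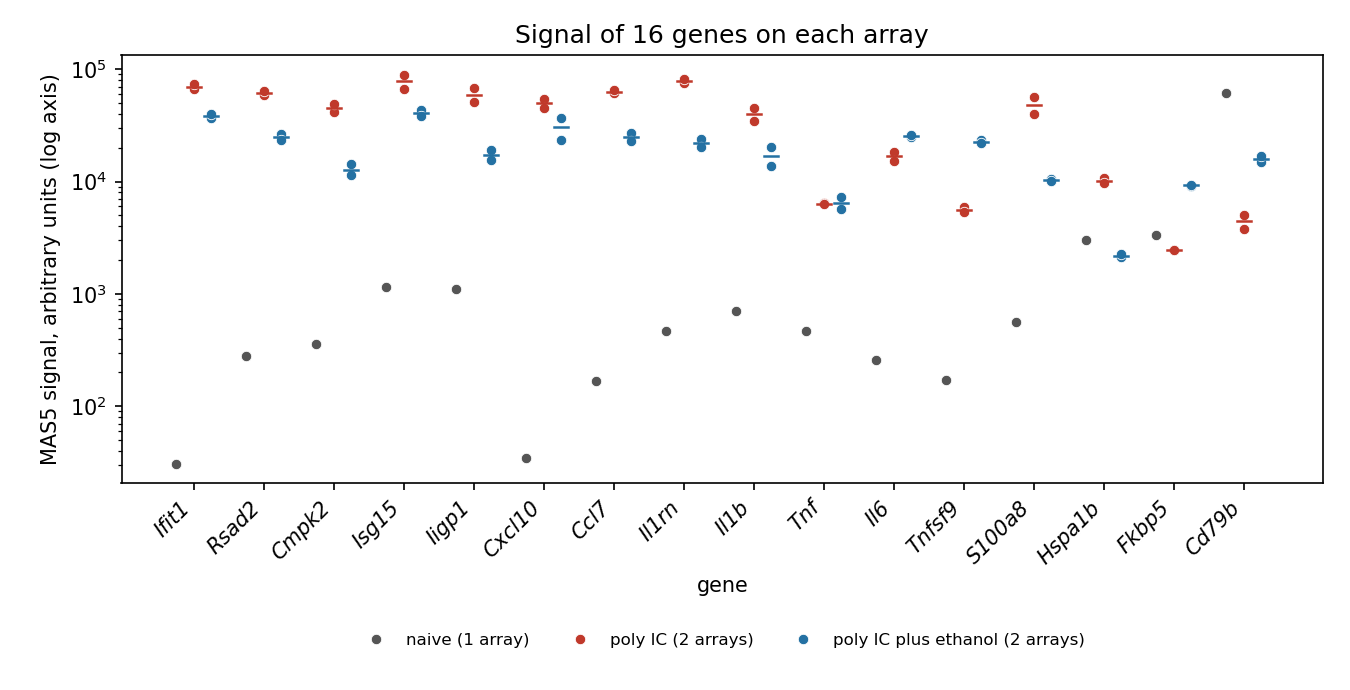
Signals of 16 genes (arbitrary units, log axis) on each of the 5 arrays, with points for single arrays coloured by group and short bars at the means of the 2 arrays of either treated group. Cmpk2 lies at 360 on the naive array, at a mean of 45636 with poly IC and at a mean of 12783 with poly IC plus ethanol, whereas Tnf has means of 6375 and 6488 in the treated groups and Tnfsf9 rises from a mean of 5638 to 22606.

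Poly IC plus ethanol against poly IC was the comparison closest to the question of the series. No array came from mice given ethanol alone. A change in the response to poly IC therefore cannot be told apart from an effect that ethanol has by itself. Most tested genes of the interferon lists fell with ethanol. Cmpk2, which encodes a mitochondrial nucleotide kinase, fell from 45636 ± 5590 to 12783 ± 2022 (n = 2 each, log2 difference -1.82, SE 0.16, adjusted p = 0.00034), against 360 on the naive array. Ms4a4c fell from 7842 ± 752 to 2050 ± 72 (-1.81, SE 0.17) and Rsad2 from 62041 ± 3444 to 25143 ± 2285 (-1.30, SE 0.13). Irf7 fell from 19883 ± 5808 to 9775 ± 747 (-0.98, SE 0.20; -0.45 and adjusted p = 0.161 on its other probe set), Isg15 from 78202 ± 16196 to 40740 ± 3250 (-0.92, SE 0.15) and Ifit1 from 70276 ± 5260 to 38616 ± 2260 (-0.86, SE 0.13, adjusted p = 0.00375). Of 42 interferon-stimulated genes, 29 fell and 1 rose, and 32 and 2 when adjusted over the list alone. Their median was -0.73 (camera adjusted p = 2.58e-21, and adjusted p = 0.335 with an estimated correlation), beside -0.85 for neutrophil markers and 0.61 for B cell markers. The gene that rose was again Ifi30 (0.69, SE 0.16, adjusted p = 0.0277), named after its value was seen. Mx2, chosen after its value was seen, was 27342 and 26435 with poly IC and 24808 and 27280 with ethanol (-0.05, SE 0.13, adjusted p = 0.87). Of the 9 interferon-gamma-inducible GTPases, 7 fell, and 9 when adjusted over the list alone. Their median was -0.63 (camera adjusted p = 3.11e-09, and adjusted p = 0.335 with an estimated correlation). Iigp1 fell from 59382 ± 12240 to 17366 ± 2685 (-1.75, SE 0.17), with smaller falls for Gbp2 (-0.80, SE 0.12) and Igtp (-0.72, SE 0.13). With 1 poly IC array left out, some calls were lost. Without replicate 2 the log2 differences of Ifit1, Isg15, Irf7, Igtp and Ifi30 were -0.78, -0.71, -0.68, -0.67 and 0.44, and without replicate 1 that of Igtp was -0.77. With eBayes without the trend the calls of Ifit1, Isg15, Irf7, Gbp2, Igtp and Ifi30 were lost, and that of Ifi30 also with median-centred arrays or no filter.

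Chemokine and cytokine genes divided. Cxcl9, an interferon-gamma-induced T cell chemokine, fell from 5452 ± 371 to 1047 ± 171 (n = 2 each, log2 difference -2.14, SE 0.21, adjusted p = 0.000537). Ccl7 fell from 63272 ± 2988 to 24854 ± 2874 (-1.34, SE 0.13), with smaller falls for Ccl5 (-0.67, SE 0.12), Ccl2 (-0.52, SE 0.13) and Cxcl10 (-0.74, SE 0.20, adjusted p = 0.0465). Of 19 chemokines, 8 fell, and 9 when adjusted over the list alone. Their median was -0.55 (camera adjusted p = 6.56e-06, and adjusted p = 0.335 with an estimated correlation). In the inflammatory list, 11 of 44 genes fell and 2 rose, and 13 and 2 when adjusted over the list alone. Their median was -0.26 (camera adjusted p = 7.45e-06, and adjusted p = 0.335 with an estimated correlation). Neutrophil markers fell in the same comparison (median -0.85, camera adjusted p = 1.62e-08, and 0.335 with an estimated correlation and 0.121 with fry). Il1rn fell from 78870 ± 4983 to 22120 ± 2573 (-1.83, SE 0.13), the prostaglandin E synthase Ptges from 31382 ± 2638 to 10226 ± 2047 (-1.61, SE 0.16) and Il1b from 39783 ± 7705 to 17031 ± 4774 (-1.23, SE 0.20). Tnfsf9, a costimulatory ligand of the tumour necrosis factor family, rose from 5638 ± 400 to 22606 ± 961 (1.96, SE 0.15, adjusted p = 0.000205). Il6 rose from 16731 ± 2208 to 25348 ± 853 (0.60, SE 0.15, adjusted p = 0.0311). For Tnf the difference was 0.02 (SE 0.17, adjusted p = 0.972), for Il10 -0.20 (SE 0.23, adjusted p = 0.64) and for Il12b -0.18 (SE 0.24, adjusted p = 0.695). Nos2 missed the threshold (-1.03, SE 0.31, adjusted p = 0.0635). It passed without the naive array (-1.03, adjusted p = 0.0414) and without ethanol replicate 2 (-1.10, adjusted p = 0.04), within a range of 0.0166 to 0.445 over its alternatives. Several calls needed both poly IC arrays. Without replicate 1 the log2 differences of Ccl2, Cxcl10, Il1b and Il6, their calls lost, were -0.60, -0.60, -1.03 and 0.73. Without replicate 2 those of Ccl2, Ccl5, Cxcl10 and Il6 were -0.44, -0.53, -0.87 and 0.46, and without ethanol replicate 2 that of Cxcl10 was -0.41. Those of Ccl2, Ccl5, Cxcl10, Il1b and Il6 were lost with eBayes without the trend. Median-centred arrays lost those of Il6 and Cxcl10, no filter those of Il6, Ccl2 and Cxcl10, and quantile normalization those of Ccl2 and Cxcl10. The call of Cxcl10 was also lost with an offset of 16 or the mean over probe sets.

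Antigen presentation genes again moved in both directions, opposite to those with poly IC. Both comparisons use the poly IC arrays, which by itself favours opposite signs: the correlation across genes was -0.407 in simulations without any effect. In the class I list, 4 of 14 genes fell, and 6 when adjusted over the list alone. Their median was -0.34 (camera adjusted p = 7.95e-06, and adjusted p = 0.335 with an estimated correlation). They were the immunoproteasome subunits Psmb10 (-0.71, SE 0.12), Psmb9 (-0.69, SE 0.14) and Psmb8 (-0.55, SE 0.11) and, named after its value was seen, Tap1 (-0.50, SE 0.12). In the class II list, 4 of 14 genes rose, also when adjusted over the list alone. Their median was 0.30 (camera adjusted p = 0.00712, and adjusted p = 0.335 with an estimated correlation). These were H2-Ob (0.90, SE 0.17), H2-DMa (0.61, SE 0.12), H2-DMb2 (0.57, SE 0.13) and Ifi30 (0.69, SE 0.16), and B cell markers rose in the same comparison. The other H2-DMa probe set did not pass (0.13, adjusted p = 0.755). Without poly IC replicate 1, the calls of Psmb8, Psmb9, Tap1, H2-DMa, H2-DMb2 and H2-Ob were lost at log2 differences of -0.61, -0.77, -0.57, 0.61, 0.64 and 0.77. Without replicate 2, those of Psmb8, Psmb9, Psmb10, Tap1, H2-DMa, H2-DMb2 and Ifi30 were lost at -0.49, -0.61, -0.61, -0.43, 0.61, 0.49 and 0.44. All 8 genes named here lost their calls with eBayes without the trend. Those of H2-DMb2 and Ifi30 were lost with median-centred arrays, of Tap1 and Ifi30 with no filter, of Tap1 with quantile normalization and of H2-DMa with the mean over probe sets.

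Part of the heat shock list fell with ethanol. The inducible Hsp70 genes Hspa1b and Hspa1a fell from 10223 ± 742 to 2196 ± 98 (n = 2 each, log2 difference -2.10, SE 0.16, adjusted p = 0.000205) and from 8824 ± 1988 to 2482 ± 186 (-1.72, SE 0.19). Their naive signals were 2993 and 5799. The constitutive Hspa8 fell by 0.76 (SE 0.13), a call lost without poly IC replicate 1 (-0.64) and with eBayes without the trend. Of 25 genes on the heat shock and endoplasmic reticulum stress list, 7 fell, and 12 when adjusted over the list alone. Their median was -0.39 (camera adjusted p = 9.07e-08, and adjusted p = 0.335 with an estimated correlation), beside -0.85 for neutrophil markers and 0.61 for B cell markers.

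Genes outside these groups also moved with ethanol. Ch25h, which makes the antiviral oxysterol 25-hydroxycholesterol, fell furthest on the offset scale (9571 ± 2870 to 1040 ± 21, n = 2 each, -2.90, SE 0.22, adjusted p = 0.000205). The BMP target Id1 fell from 2508 ± 426 to 482 ± 126 (-1.92, SE 0.24, with 1 ethanol array below the brightest unspiked control) and the MYC antagonist Mxd1 from 7336 ± 1136 to 1817 ± 6 (-1.87, SE 0.19). The vasodilator peptide gene Adm rose from 7581 ± 772 to 27328 ± 1216 (1.82, SE 0.14) and Fkbp5, a co-chaperone of the glucocorticoid receptor, from 2457 ± 31 to 9243 ± 197 (1.81, SE 0.15). The mitochondrial acetyl-CoA synthetase Acss1 rose from 1300 ± 476 to 4868 ± 896 (1.75, SE 0.23), Phlda1 by 1.69 (SE 0.21) and Fam107b by 1.66 (SE 0.14). Mapk14, which poly IC lowered, rose from 4246 ± 592 to 13351 ± 1260 (1.60, SE 0.15). The glucocorticoid-responsive list that holds Fkbp5 did not pass (camera adjusted p = 0.289), with 2 of 29 genes up and 4 down, and 3 and 4 when adjusted over the list alone. Without ethanol replicate 1 it passed downward (adjusted p = 0.0372, within a range of 0.0372 to 0.824 over its alternatives). Klf9 also rose (0.81, SE 0.17), and Cebpd (-0.86, SE 0.11), Cebpb (-0.75, SE 0.12), Klf4 (-0.84, SE 0.21) and Lcn2 (-0.80, SE 0.20) fell. The other Lcn2 probe set did not pass and had the opposite sign (0.11, adjusted p = 0.847). Of these, Klf9, Klf4 and Lcn2 were named after their values were seen. Their calls were lost without poly IC replicate 2, at log2 differences of 0.89, -0.52 and -0.91. Those of Klf9 and Lcn2 were also lost without poly IC replicate 1, at 0.72 and -0.68, and that of Lcn2 without ethanol replicate 2, at -0.54. With eBayes without the trend the calls of Cebpd, Cebpb, Klf9, Klf4 and Lcn2 were lost, with no filter those of Klf4 and Lcn2, and with the mean over probe sets that of Lcn2.

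Cell type markers differed between the treated groups too. Of 16 neutrophil markers, 6 fell and none rose, and 11 fell and 1 rose when adjusted over the list alone. Their median was -0.85 (camera adjusted p = 1.62e-08, and adjusted p = 0.335 with an estimated correlation). S100a8 fell from 48580 ± 11651 to 10425 ± 305 (n = 2 each, log2 difference -2.17, SE 0.17) and S100a9 from 25908 ± 7636 to 5511 ± 234 (-2.15, SE 0.20). The collagenase Mmp8 fell from 1981 ± 1024 to 128 ± 20, below the brightest unspiked control and so at least 4.46-fold. Its call was lost without poly IC replicate 1, at a log2 difference of -1.99. Of 16 B cell markers, 7 rose, and 9 when adjusted over the list alone. Their median was 0.61 (camera adjusted p = 7.26e-06, and adjusted p = 0.335 with an estimated correlation). Cd79b rose from 4436 ± 888 to 15993 ± 1470 (1.80, SE 0.16), the kinase gene Blk from 6524 ± 900 to 16759 ± 602 (1.33, SE 0.14) and Spib from 1505 ± 385 to 4101 ± 449 (1.32, SE 0.20). The other Spib probe set did not pass (0.12, adjusted p = 0.796). The naive signals of these genes were 62100, 23875 and 12717. Hba-a1, chosen after its value was seen, was 14985 and 7794 on the ethanol arrays (-0.83, SE 0.32, adjusted p = 0.129). The list of resident peritoneal macrophage markers did not pass (camera adjusted p = 0.643), with a median of -0.00618, a mean of 0.0217 and a downward test. Of its 23 genes, the adhesion receptor Selp (-0.41, SE 0.11) and Cebpb fell, and 1 fell when adjusted over the list alone. The Selp call was lost without the naive array (-0.41), poly IC replicate 1 (-0.47), poly IC replicate 2 (-0.35) or ethanol replicate 2 (-0.28), and with median-centred arrays, quantile normalization, no filter, the mean over probe sets or the 4 treated arrays alone. The calls of Selp, Cebpb and Spib were lost with eBayes without the trend. Inflammatory monocyte markers as a list did not pass either (camera adjusted p = 0.488), with a median of 0.0744, a mean of -0.254 and a downward test. Of its 8 genes, the proteoglycan gene Vcan fell from 8477 ± 3 to 2658 ± 689 (-1.61, SE 0.19) and the Fc receptor gene Fcgr1 from 29785 ± 5035 to 10562 ± 2056 (-1.48, SE 0.17), both also when adjusted over the list alone. Mast cell markers did not pass as a list (camera adjusted p = 0.488, median 0.00507, mean -0.0778, downward test), and 1 of 8 fell on both counts. The list passed downward with no filter (camera adjusted p = 0.0316) and with poly IC replicate 2 left out, and its adjusted p reached 0.842 over its alternatives. The member that fell was the histidine decarboxylase gene Hdc, which activated myeloid cells also express (26970 ± 2097 to 11988 ± 1020, -1.15, SE 0.14).

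**Figure D2:**
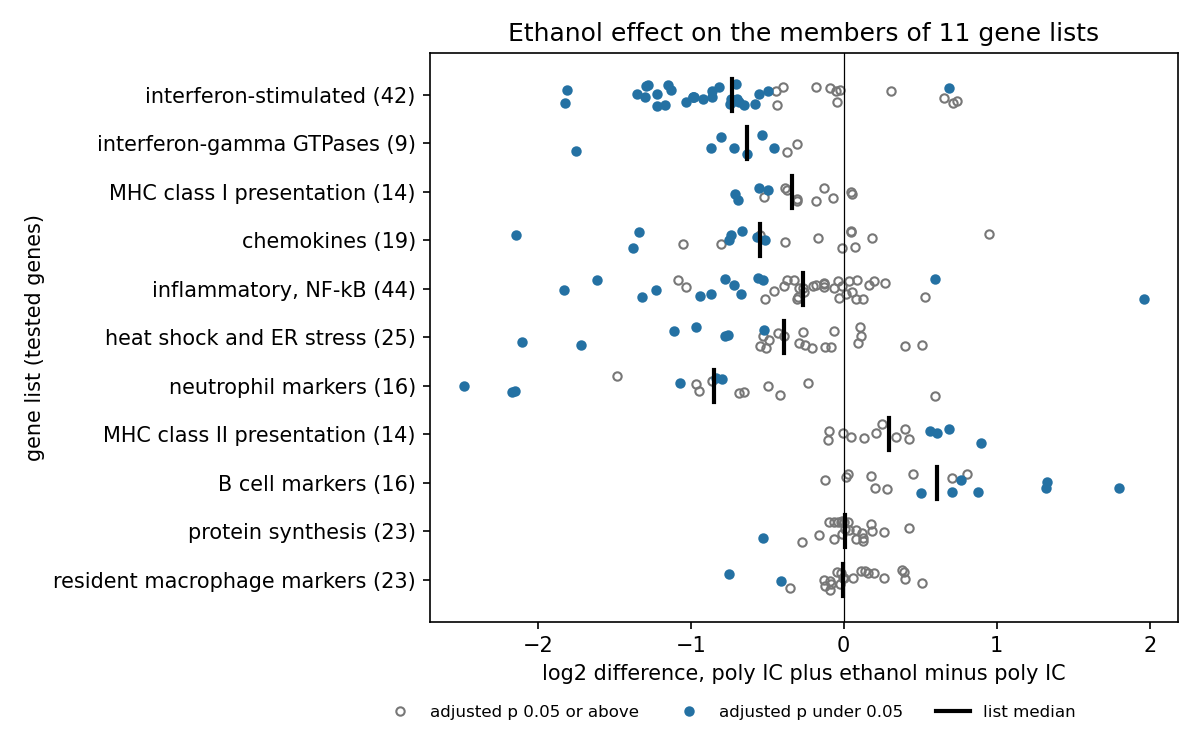
Log2 differences of single genes between poly IC plus ethanol and poly IC (horizontal axis) for 11 gene lists, with the number of tested genes in brackets, filled points for adjusted p under 0.05, open points for the rest and a vertical bar at each list median. Medians lie at -0.73 for interferon-stimulated genes, -0.85 for neutrophil markers, 0.61 for B cell markers and 0.30 for MHC class II presentation.

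In total, limma called 590 of 5581 genes between poly IC plus ethanol and poly IC, 322 higher and 268 lower. Of these, 105 and 75 were at least 2-fold apart, and 1441 genes had an unadjusted p under 0.05. The number depended on the variance estimate and on single pools. It was 86 with a common prior variance for all signal levels, 139 without poly IC replicate 2, 203 without poly IC replicate 1 and 1076 without ethanol replicate 1. Centring each array on its median gave 194 higher and 286 lower, and quantile normalization gave 291 higher and 287 lower. Which direction held more genes thus depended on the scaling chosen. No named gene that passed changed its direction in any setting. Of 23 lists, 9 passed camera, 2 up and 7 down. With an estimated correlation, which leaves 2 degrees of freedom for the test, none of them passed, and 2 had an unadjusted p under 0.05. fry called none at a smallest adjusted p = 0.0524, and 9 lists had an unadjusted p under 0.05.

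The effect of ethanol on genes induced by poly IC was also measured with the choice of genes and the measurement on different poly IC arrays. Genes at least 1 log2 unit above naive on one poly IC array (473 and 474 genes for the 2 ways round) had a median difference of -0.393 log2 units between the ethanol arrays and the other poly IC array. On the offset scale this is 76.2% of the poly IC level. The ways round gave -0.402 and -0.384, and the 4 pairs of an ethanol with a poly IC array ranged from -0.424 to -0.345 (SD 0.0327). All tested genes had a median of 0.0698, and 10000 random lists matched on signal ranged from -0.0282 to 0.0729. Of the induced genes, 78.4% and 78.5% were lower with ethanol than on the other poly IC array. The mirror measure, chosen after the data were seen, was made on genes at least 1 log2 unit lower with poly IC (683 and 784 genes). It gave 0.508 (0.563 and 0.453 for the ways round), against 0.0467 to 0.134 for random lists.

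By single calls, 208 of the 654 genes raised by poly IC fell with ethanol (31.4 for independent lists) and 16 rose (37.7 for independent lists). Of the 1121 genes lowered by poly IC, 261 rose with ethanol (64.7 for independent lists) and 6 fell (53.8 for independent lists). Both comparisons use the poly IC arrays. Across genes, their effects correlated at -0.62, against -0.407 in simulations without any effect. Limma called 491 genes in both comparisons. The simulations gave 0, but without effects hardly any gene is called in either comparison. That count therefore cannot show how much overlap the shared arrays add. The covariance was -0.278, against -0.0279 simulated. With no shared array, the correlation was -0.526 or -0.486 and the covariance -0.258 or -0.235. Part of the excess in the overlaps may come from the shared arrays.

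**Figure D3:**
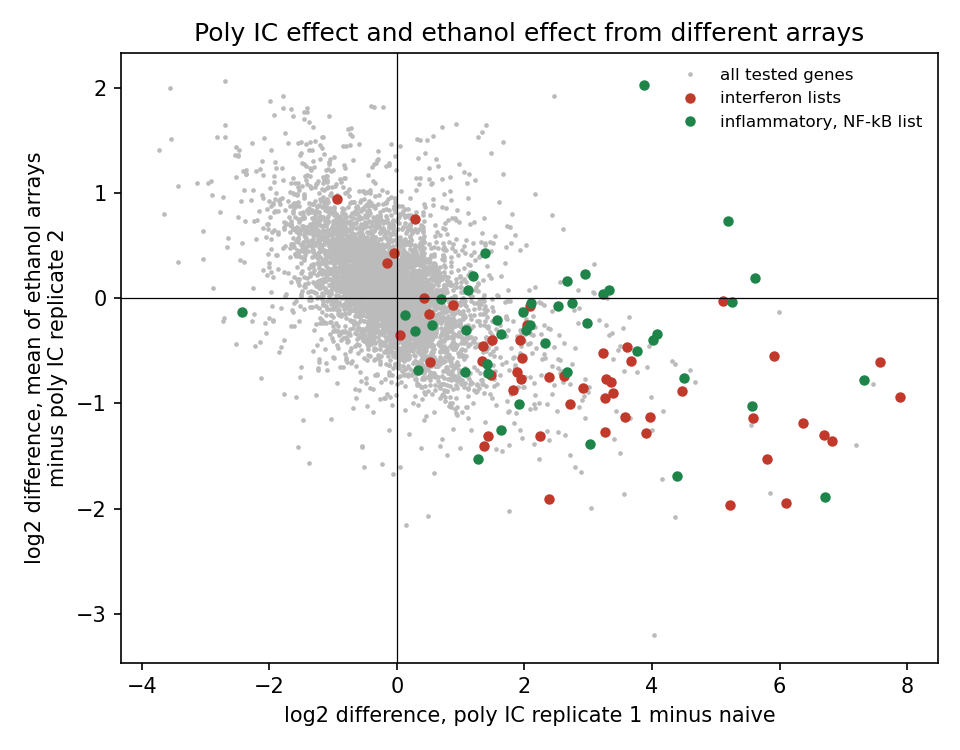
Each point is 1 of 5581 genes, with the log2 difference of poly IC replicate 1 from naive on the horizontal axis and that of the mean of the ethanol arrays from poly IC replicate 2 on the vertical axis, so that the axes share no array. Coloured points mark members of the interferon lists and of the inflammatory list, and the correlation across genes is -0.526.

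Poly IC plus ethanol against naive showed the joint effect of both treatments, whose parts cannot be separated without an array of ethanol alone. Ifit1 was at 38616 ± 2260 (n = 2) against 31 on the naive array, at least 128-fold higher (adjusted p = 3.22e-09). Other genes with naive signals below the brightest unspiked control rose at least 172-fold (Acod1), 127-fold (Ccl4), 101-fold (Cxcl10), 84-fold (Il6), 83.3-fold (Rsad2), 74.9-fold (Tnfsf9), 5.79-fold (Il10) and 4.52-fold (Il12b). Mt2 rose by 5.94 (SE 0.11) and Il1a by 5.59 (SE 0.16) log2 units. Il1b, Adm and Tnf rose by 4.14, 4.19 and 3.22 log2 units, and Isg15, Irf7, Ccl2 and Ccl5 by 4.88, 2.59, 3.87 and 4.14. Nos2 did not pass (adjusted p = 0.175). Among interferon-stimulated genes 32 of 42 rose, and 35 rose and 1 fell when adjusted over the list alone (median 1.75, camera adjusted p = 2.82e-35). All 9 interferon-gamma-inducible GTPases rose on both counts (median 2.61, camera adjusted p = 4.06e-15). Of 44 inflammatory genes 35 rose and 1, Ltb, fell, with 36 and 1 when adjusted over the list alone (median 1.89, camera adjusted p = 9.57e-36). Of 19 chemokines 14 rose on both counts (median 2.09, or 1.79 with 9 dim members at their bounds, camera adjusted p = 4.06e-15). The adjusted p was 0.26 with an estimated correlation for each of these 4 lists.

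Antigen presentation, cell type and stress lists were also tested against naive. In the MHC class II list 4 of 14 genes fell, and 5 when adjusted over the list alone. The 4 were H2-Ob (log2 difference -0.96, SE 0.20), H2-DMb2 (-0.81, SE 0.16), H2-DMa (-0.62, SE 0.14) and, named after its value was seen, H2-Ab1 (-0.48, SE 0.14). Their median was -0.39 (camera adjusted p = 0.0122, and adjusted p = 0.446 with an estimated correlation). In the class I list Tap1 (1.53, SE 0.14) and Psmb10 (0.54, SE 0.15) rose of 14 genes, also when adjusted over the list alone (camera adjusted p = 0.0581). Of 16 B cell markers 8 fell and 1 rose, and 11 and 1 when adjusted over the list alone, with Cd79b at -1.94 (SE 0.20), Spib at -1.58 (SE 0.24) and the rise that of Cd83 (2.54, SE 0.16). Their median was -0.64 (camera adjusted p = 0.000702, and adjusted p = 0.446 with an estimated correlation). Of 16 neutrophil markers 6 rose and 2 fell, and 9 and 2 when adjusted over the list alone, with S100a8 up by 3.71 (SE 0.21) and S100a9 at least 18.3-fold. The falls, named after their values were seen, were Mmp9 (-1.16, SE 0.35) and Prtn3 (-0.95, SE 0.22). Their median was 0.72 (camera adjusted p = 6.55e-05, and adjusted p = 0.528 with an estimated correlation and 0.0802 with fry). On the heat shock list 3 of 25 genes rose and 3 fell, and 4 and 4 when adjusted over the list alone (camera adjusted p = 0.679). The rises were Atf3 (1.94, SE 0.15), Ppp1r15a (0.72, SE 0.20) and Asns (0.90, SE 0.23), and the falls Hspa1a (-1.15, SE 0.23, adjusted p = 0.0071), Herpud1 (-1.30, SE 0.25) and Dnajb1 (-1.01, SE 0.24). Of these, Ppp1r15a, Asns and Dnajb1 were named after their values were seen. Of 28 Toll-like receptor signalling components 10 rose and 2 fell, also when adjusted over the list alone. Their median was 0.19 (camera adjusted p = 0.00982, and adjusted p = 0.528 with an estimated correlation), and the falls, named after their values were seen, were Fos (-1.04, SE 0.16) and Irf5 (-0.97, SE 0.24). Of 29 glucocorticoid-responsive genes 10 rose and 8 fell, and 11 and 8 when adjusted over the list alone. Their median was 0.21 (camera adjusted p = 0.0458, and adjusted p = 0.528 with an estimated correlation). Of 28 genes of oxidative stress and ethanol metabolism 6 rose and 1, Aldh9a1 (-0.92, SE 0.25), fell, and 7 and 3 when adjusted over the list alone. Their median was 0.26 (camera adjusted p = 0.0447, and adjusted p = 0.446 with an estimated correlation), and Aldh9a1 was named after its value was seen. Of 23 complement and phagocytic receptors 6 rose, also when adjusted over the list alone. Their median was 0.19 (camera adjusted p = 0.00305, and adjusted p = 0.528 with an estimated correlation and 0.131 with fry). The list of inflammatory monocyte markers did not pass (camera adjusted p = 0.362, median 0.114), and of its 8 genes 2 rose and 1 fell on both counts. The calls of H2-Ab1, Psmb10, Ppp1r15a, Asns and Aldh9a1 were lost without poly IC replicate 1 or without poly IC replicate 2, at the same log2 differences of -0.48, 0.54, 0.72, 0.90 and -0.92, as these arrays enter only through the variance. With eBayes without the trend the calls of these 5 genes and of H2-DMa, H2-DMb2, H2-Ob, Dnajb1, Irf5, Mmp9 and Prtn3 were lost, and with no filter those of the same 5 and of Dnajb1, Irf5 and Mmp9. Median-centred arrays lost those of H2-Ab1, H2-DMa, Aldh9a1, Irf5 and Mmp9, and quantile normalization those of Aldh9a1 and Mmp9. The mean over probe sets lost those of H2-Ab1 and Mmp9, and an offset of 1000 that of Mmp9. Among the falls were the erythroid and megakaryocyte factor Nfe2 (5605 to 487 ± 235, -3.03, SE 0.35, with 1 ethanol array below the brightest unspiked control), Sema4b (-2.79, SE 0.31; -0.31 and adjusted p = 0.507 on its other probe set), the ERK phosphatase Dusp6 (-2.79, SE 0.24), Ccr2 (-2.72, SE 0.37) and Rgs2 (-2.68, SE 0.22).

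Against naive, limma called 929 genes with poly IC plus ethanol, 468 higher and 461 lower, and 555 of them were at least 2-fold apart. The median of all genes was -0.108 log2 units, and median-centred arrays gave 497 higher and 270 lower. A common prior variance gave 579 genes in all, and the fit without ethanol replicate 1 gave 1520. Of 23 lists 11 passed camera, 9 up and 2 down. With an estimated correlation, which leaves 2 degrees of freedom for the test, none of them passed. Of the lists, 4 had an unadjusted p under 0.05 in that setting. A count of 11 was also called by fry, but not of the same lists. It left out neutrophil markers (fry adjusted p = 0.0802) and complement and phagocytic receptors (0.131). In their place it called the glycolysis and hypoxia list (0.0377) and dendritic cell markers (0.0455). Both treated groups shared 415 raised genes (54.8 for independent lists) and 404 lowered genes (92.6 for independent lists). Their effects correlated at 0.894 across genes (0.667 simulated without effects), with a covariance of 0.701 (0.056 simulated). Limma called 819 genes in both. The simulated count of 0.15 cannot show how much overlap the shared array adds, as the simulations held no effects. Part of the excess over independent lists may come from the shared naive array.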

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

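The signals in this part were singled out after their values were seen, as they come from probe sets that no comparison used and exceed the naive array or change between groups. The 3' probe set for 18S ribosomal RNA had a signal of 66548 in poly IC replicate 2 and 19415 in ethanol replicate 2, against 7277 on the naive array. Among 778 probe sets without a single gene symbol, limma called 183 between poly IC and naive and 14 between poly IC plus ethanol and poly IC. A control probe set for mouse Fas, the death receptor gene, averaged 5579 on the poly IC arrays against 1142 on the naive array. A control probe set for mouse Il10 averaged 1707 on the poly IC arrays against 63 on the naive array. No explanation was tested for these signals.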

How the results depend on the processing

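The alternatives in this part were all chosen in advance, and the cause of the shifts was not tested. For poly IC plus ethanol against poly IC, the count of 590 genes became 324 without a filter, 86 with eBayes without the trend, 913 at adjusted p under 0.10 and 139 to 1076 with 1 array left out. For poly IC against naive, leaving out 1 array gave 1158 to 2367 in place of 1775. For poly IC plus ethanol against naive, eBayes without the trend gave 579 and leaving out 1 array 720 to 1520 in place of 929. The remaining alternatives moved these counts by less than 1.5 times, and no gene called both as reported and under an alternative changed direction. The ethanol effect on induced genes (-0.393) was -0.437 without cross-fitting, -0.629 for genes raised by at least 2 log2 units, -0.429 with an offset of 1000, -0.326 without a filter, -0.43 with the 60th percentile filter and -0.439 with median-centred arrays, beyond the SD of 0.0327 over array pairs but in the same direction; with an offset of 16, quantile normalization or either ethanol array left out it lay within that SD. For ethanol against poly IC, called lists went from 9 to 0 with an estimated correlation in camera (2 at unadjusted p under 0.05) and to 0 with fry (9 at unadjusted p under 0.05). For poly IC against naive they went from 11 to 0 with an estimated correlation (4 at unadjusted p under 0.05), while fry gave 14 that held 10 of the 11. Lists were otherwise rerun only with quantile normalization, an offset of 16, no filter or 1 array left out. For ethanol against poly IC they were also rerun with the replicate number as a block. All called lists were kept in these reruns, and further lists passed in some. Of 65 printed genes called for ethanol against poly IC, 28 passed in every alternative, and eBayes without the trend lost 36. Of 91 for poly IC against naive 78 always passed, and of 46 for ethanol against naive 34. None of these changed direction. Nos2, not called for ethanol against poly IC, passed in 6 alternatives, while differences of uncalled genes that were also uncalled under the alternative changed sign in 4 cases. The pools share the numbers 1 and 2 across groups, but the labels do not say that a number marks a shared batch. The deviations of same-numbered pools correlated at 0.0501 across genes, with 2 pairs, which does not settle whether they share a batch, and the 18S signal was higher in replicate 2 of both treated groups. With the replicate number as a block, 778 genes were called, 589 of them among the 590, and 9 lists, and the 4 treated arrays without a block gave 552. Signal over background limits the dim genes: unspiked controls reached 299.6 to 443.8, close to the filter of 513.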

Other observations

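All tests of explanations in this part were chosen after the results were seen, whereas the gene and list tests were chosen in advance. Poly IC also moved genes of metabolism and of other cells. Sod2, the mitochondrial superoxide dismutase, rose from 2123 to 27936 ± 2872 (n = 2 against 1, log2 difference 3.57, SE 0.16), the thioredoxin reductase Txnrd1 by 2.80 (SE 0.16) and the antioxidant regulator Nfe2l2 by 1.96 (SE 0.16). On the list of oxidative stress and ethanol metabolism 6 of 28 genes rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.0617). The list passed upward with fry (adjusted p = 0.0261) and with poly IC replicate 1 or ethanol replicate 1 left out. Its adjusted p ranged from 0.0261 to 0.316 over its alternatives. The falls, named after their values were seen, were Aldh9a1 (-1.11, SE 0.25), the alcohol dehydrogenase Adh5 (-0.89, SE 0.18), Gstp1 (-0.86, SE 0.16) and the acetaldehyde-oxidising Aldh2 (-0.47, SE 0.16). Other probe sets of Adh5 (-0.41, adjusted p = 0.218) and Aldh2 (-0.40 and -0.26, adjusted p = 0.127 and 0.251) did not pass. Hk2, which starts glycolysis, rose from 2610 to 29856 ± 535 (3.40, SE 0.16), Adm by 2.37 (SE 0.18) and Ldha by 0.38 (SE 0.13), whereas Pdk1 (-1.40, SE 0.25), Tpi1 (-1.08, SE 0.17) and Pgam1 (-0.72, SE 0.19) fell. These were 3 rises and 3 falls of 16 genes, also when adjusted over the list alone (camera adjusted p = 0.395, median -0.0832, mean 0.196, upward test, and 0.0494 with fry, within a range of 0.0494 to 0.771). Of 29 cell cycle genes Mki67 rose (1.88, SE 0.29; 0.52 and adjusted p = 0.4 on its other probe set) and 6 fell, among them Mcm7 (-1.37, SE 0.30), and 1 and 3 when adjusted over the list alone (camera adjusted p = 0.0841, and 0.0187 without a filter, downward, within a range of 0.0187 to 0.476). On the cholesterol and lipid list the desaturases Scd1 (-1.47, SE 0.14) and Scd2 (-2.12, SE 0.25) fell of 15 genes, also when adjusted over the list alone (camera adjusted p = 0.261). Of 9 T and NK cell markers the granzymes Gzmb (at least 13.8-fold) and Gzma (1.27, SE 0.32) rose, and Cd2 (-1.32, SE 0.21) and Klrd1 (-1.12, SE 0.38) fell, also when adjusted over the list alone (camera adjusted p = 0.422). Of 9 dendritic cell markers Fscn1 (0.72, SE 0.21) rose, and Ltb (-2.32, SE 0.18), Irf4 (-2.26, SE 0.20), Ccr7 (-1.72, SE 0.28) and H2-DMb2 (-1.38, SE 0.16) fell, also when adjusted over the list alone (camera adjusted p = 0.0815). The list passed downward with fry (adjusted p = 0.0261), with no filter (camera adjusted p = 0.0239) and with poly IC replicate 2, ethanol replicate 1 or ethanol replicate 2 left out. Its adjusted p ranged from 0.0239 to 0.484. Of 8 mast cell markers Hdc (3.35, SE 0.17) and Srgn (1.43, SE 0.17) rose, also when adjusted over the list alone (camera adjusted p = 0.0757). The list passed upward with no filter (camera adjusted p = 0.0121) and with poly IC replicate 2 left out, but not with fry (adjusted p = 0.153). Of these genes Ldha, Pdk1, Pgam1, Klrd1, Ccr7 and Fscn1 were also named after their values were seen. Without poly IC replicate 1 the calls of Aldh2, Ldha, Pgam1, Gzma and Klrd1 were lost at -0.55, 0.44, -0.77, 1.22 and -1.14, and without replicate 2 those of Aldh2, Ldha, Pgam1, Gzma, Klrd1 and Fscn1 at -0.40, 0.32, -0.68, 1.31, -1.10 and 0.53. With eBayes without the trend the calls of Aldh2, Ldha and Fscn1 were lost, with median-centred arrays those of Aldh2, Klrd1 and Pgam1, and with no filter those of Aldh2, Ldha and Klrd1. Quantile normalization lost those of Ldha and Klrd1, the mean over probe sets that of Aldh2, and an offset of 16 that of Klrd1.

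With ethanol against poly IC, some genes rose on lists that did not pass as a whole. Scd1 rose from 12102 ± 671 to 26452 ± 53 (n = 2 each, log2 difference 1.11, SE 0.12, adjusted p = 0.000741) and Scd2 from 830 ± 118 to 1643 ± 215 (0.81, SE 0.21), 2 of 15 cholesterol and lipid genes on both counts (camera adjusted p = 0.643). The thymidine kinase Tk1 (1.14, SE 0.21) and Hmgb2 (0.93, SE 0.20) rose, 2 of 29 cell cycle genes on both counts (camera adjusted p = 0.488). Of 16 glycolysis and hypoxia genes Adm and Pfkl (0.62, SE 0.15) rose, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.788). Of 28 Toll-like receptor signalling components Mapk14 and Jun (0.65, SE 0.17) rose and Irf7 fell, also when adjusted over the list alone (camera adjusted p = 0.289). Fcgr1 and Clec4e (-0.71, SE 0.15) fell, 2 of 23 complement and phagocytic receptors on both counts (camera adjusted p = 0.12, and 0.00995 without poly IC replicate 1 and 0.0064 without ethanol replicate 1, both downward, within a range of 0.0064 to 0.774). Cd2 rose from 8722 ± 2208 to 17910 ± 803 (1.04, SE 0.17) and Gzmb fell from 4158 ± 1592 to 1255 ± 277 (-1.51, SE 0.27), 1 each of 9 T and NK cell markers, and 1 and 2 when adjusted over the list alone (camera adjusted p = 0.406). Irf4 (0.72, SE 0.16) and H2-DMb2 rose, 2 of 9 dendritic cell markers on both counts (camera adjusted p = 0.561). Ncl fell (-0.53, SE 0.12), 1 of 23 protein synthesis genes on both counts (camera adjusted p = 0.759, median 0.0061, mean 0.0171, downward test). On the list of oxidative stress and ethanol metabolism limma called 0 of 28 genes on both counts (camera adjusted p = 0.488, median 0.0452, mean -0.00925, downward test). Without poly IC replicate 1 the calls of Scd2, Hmgb2, Pfkl, Jun, Clec4e, Gzmb, Irf4, H2-DMb2 and Ncl were lost at 0.92, 0.97, 0.71, 0.51, -0.77, -1.14, 0.74, 0.64 and -0.52. Without replicate 2 those of Scd2, Tk1, Hmgb2, Pfkl, Jun, Irf7, Clec4e, Irf4, H2-DMb2 and Ncl were lost at 0.70, 1.01, 0.88, 0.52, 0.78, -0.68, -0.64, 0.70, 0.49 and -0.54, and without the naive array that of Scd2 at 0.81. With eBayes without the trend the calls of Scd2, Tk1, Hmgb2, Pfkl, Jun, Irf7, Clec4e, Cd2, Gzmb, Irf4, H2-DMb2 and Ncl were lost. Median-centred arrays lost those of Scd2, Pfkl, Jun and H2-DMb2, no filter those of Scd2, Hmgb2, Jun and Ncl, quantile normalization those of Scd2, Jun and Ncl, and the 4 treated arrays alone that of Scd2.

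With ethanol 29 of 42 interferon-stimulated genes and 11 of 44 inflammatory genes fell, list calls that were lost with an estimated correlation (adjusted p = 0.335 for both) and with fry (adjusted p = 0.0524 and 0.121), while 6 of 16 neutrophil markers fell as well. Cells that did not respond to poly IC, diluting the ethanol pools, would lower both by the same share, but among genes raised at least 3 log2 units the median of 16 inflammatory genes (-0.294) lay 0.629 above that of 23 interferon genes (-0.923), and 0.557 to 0.64 above it over the 4 array pairs. If the same cells express both sets, which was not tested, this argues against dilution as the whole cause. The 4 pairs reuse the same arrays, so their range is not an independent spread. The comparison was also picked after the lists were seen to differ. Signals near the top of the array range could hide a fall of the cytokine genes, but among members below a signal of 39800 the difference was 0.689 (10 interferon and 9 inflammatory genes, 0.536 to 0.683 over the pairs, permutation p = 0.0707 across genes, which are not independent). A smaller effect of ethanol on the inflammatory than on the interferon genes remains a hypothesis, found and tested on the same data.

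With ethanol 6 of 16 neutrophil markers fell and 7 of 16 B cell markers rose, list calls that were lost with an estimated correlation (adjusted p = 0.335 for both) and with fry (adjusted p = 0.121 and 0.0524). A lower share of neutrophils in the ethanol pools may account for the first. All 7 markers dim on the naive array had negative log2 differences (-2.48 to -0.796), 3 of them called. Of the 7, 6 were lower in both ethanol arrays than in both poly IC arrays, while the arrays of Ngp were not fully apart. Markers dim on the naive array pass the filter only if they are brighter on treated arrays. Among genes induced by poly IC, 78.4% and 78.5% were lower with ethanol for the 2 ways round. Neither count therefore singles out a change in neutrophils. Activated macrophages also make Lcn2, so a lower share of neutrophils stays open as an explanation. A higher share of B cells in the ethanol pools as the whole cause of the B cell marker rise stays open too. Of the 12 markers that poly IC lowered, 7 lay over 2 SE from their common value of 0.65 (-0.125 to 1.8), but the probe sets of Spib alone lay 1.2 log2 units apart, so the spread does not decide.

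Fkbp5 and Klf9, which glucocorticoids induce, were higher with ethanol. A response to glucocorticoid across its target genes may be the cause, but the list of such genes had a camera adjusted p = 0.289, a median of -0.0603 and a downward test, which passed without ethanol replicate 1 (adjusted p = 0.0372, against the explanation, within a range of 0.0372 to 0.824). Genes of the list moved both ways and the call rests on leaving out 1 array, so the test does not decide, and Tsc22d3, a target named in advance, was below the filter. No hormone was measured here, and ethanol, stress of dosing and other inducers of these genes cannot be told apart.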
